A study of Homo sapiens with 287 samples.

How the data were processed

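The series profiled regions of formalin-fixed metastases of HER2-positive breast cancer, taken before treatment with trastuzumab deruxtecan, with the NanoString GeoMx platform. In this assay DNA-barcoded probes are released by light from a chosen region and counted by sequencing. Per the labels, the series holds 287 samples. Those with a deposited count file numbered 190. The first plate combined whole-transcriptome RNA probes with DNA-barcoded antibodies in the same regions, and the second plate carried RNA probes alone. Per the submitters' notes, regions were chosen by hand from morphology, guided by stains for pan-cytokeratin, CD45 and nuclei. They were then segmented into tumour areas positive for pan-cytokeratin and immune areas positive for CD45. The labels give the tissue of each region. Patient, treatment response and segment are not given there, and the patient workbooks that the submitters mention were not used here.

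The deposited count file of each region holds whole counts of deduplicated barcodes, not expected or estimated counts. Per the file headers, it came from the GeoMx NGS Pipeline version 3.1.1.8. The submitters' notes name the human build GRCh38, and the aligner is not given in the sources used here. The deposited gene tables hold raw counts for 86 regions of the first plate and 76 of the second. The first table lists 10768 genes with every 0 written as 1. Each of its values equalled the larger of 1 and the count in the region's own file (100% of values), and 16.0% of the values were 0 in those files. The second table lists 18676 genes. The rule that selected the genes of the first table is not given in the sources used here. Each of the 18676 genes was tied to 1 barcode by its counts in the regions, and 18668 had a RefSeq symbol or synonym. A row for the negative probes, whose targets are absent from the human transcriptome, held 0.00146% and 0.00188% of the 2 tables and stayed out of library totals and tests.

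Genes of the Y chromosome, the genes XIST and TSIX, and genes absent in many people through a common inherited deletion were left out by rule, 5 from the first table and 32 from the second. This left 10763 and 18644 genes. On the second plate the 25% of genes with the lowest mean were also left out of the test. The first table had already been filtered by the authors, so no further filter was applied there. Background was read from 139 negative probes in each region. A gene exceeded the limit of quantification in a region where its count passed both 2 and the geometric mean of the negative probes times their geometric SD raised to the power 2.

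Groups were taken from the labels. The first plate gave 47 bone and 39 brain regions, and the second gave 61 bone and 15 chest wall regions; the plates were never pooled. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust quasi-likelihood fit, two-sided, tissue as the only term, Benjamini-Hochberg adjustment). A gene was called at an adjusted p under 0.05 and a fold change of at least 2. Levels are log2 CPM (counts scaled to a common total) with a prior count of 2, and all differences are bone minus the other tissue. The study has 6 patients with 2 bone lesions, 2 brain lesions and 1 chest wall lesion. The submitters' notes also count a lesion of another site, which no label names, and whether its regions are among those labelled otherwise is not given in the sources used here. Regions share lesions that the labels do not identify, so p-values over regions are too small.

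Barcodes read only on the first plate numbered 580 and were taken as the antibody barcodes. Their names are not in the files. The plan had been to scale by control antibodies, which cannot be recognised without names; each region's log2 count plus 1 was instead centred on its mean over the 580 barcodes. These values were tested with limma 3.58.1 (robust moderated test, two-sided, Benjamini-Hochberg adjustment), with a call at an adjusted p under 0.05 and a fold of at least 1.5. A comparison of RNA and protein of the same target, and the adjustment for pan-cytokeratin and CD45 protein, could not be run for want of names.

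Before the data were examined, 35 gene lists were fixed, 16 of pathways and 19 of cell types. Lists with at least 3 tested genes (29 on the first plate and 34 on the second) were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Genes to be named were also fixed by rule. They were the 8 called genes with the largest difference in each direction among those whose higher mean passed the median of all genes, up to 3 members per list by adjusted p, and 12 genes fixed in advance. Members that complete a list's count are named beside it whatever their rank, after their values were seen, and any other gene named outside the rule is said to be so. The rule's genes included 1 that is not named because its probe may share sequence with a gene left out.

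Because regions were placed on the plates in stretches of adjacent wells, the tests were repeated for each stretch of bone wells against each stretch of the other tissue. This gave 4 pairs on the first plate and 2 on the second. The pairs of the first plate, and the count of genes called in every pair on either plate, were chosen after seeing the data. The 2 comparisons of the second plate were set before. Other alternatives covered the scaling (DESeq2 1.42.0 size factors, the median), DESeq2's own test, filters, thresholds, depth, the epithelial and leukocyte levels, the background share and the floor of 1. On negative binomial counts simulated at each plate's totals and dispersions, edgeR recovered 100% of genes changed 4-fold on both plates, by adjusted p and direction. It recovered 91% of those changed 2-fold on the first plate and 97% on the second, with 39 and 11 unchanged genes past the adjusted p and 2 and 1 of them called. The limma test recovered 96.7% of 60 barcodes changed 2-fold, with 1 unchanged barcode called. Regions were simulated as independent, without lesions or stretches of wells, so these rates do not cover errors from such structure. Regions were compared for repeats by chi-square per degree of freedom over 3655 pairs on the first plate and 2850 on the second. On the second plate 73 pairs had a ratio below 1.1, the smallest 1.03, but no pair agreed within counting noise at a p over 0.05, so none was left out. Left out were 28 regions with a count file but in neither table, 1 brain sample of the first plate without a count file, and 96 further samples without files whose labels conflict with those of the other samples of the same wells. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.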

Results

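RNA counts were available for 162 regions of metastases sampled before trastuzumab deruxtecan, an antibody-drug conjugate that carries a topoisomerase I inhibitor to HER2-bearing cells. The first plate held 47 regions of bone metastases and 39 of brain metastases, read for RNA and for antibodies. The second held 61 regions of bone metastases and 15 of a chest wall metastasis, read for RNA alone. Median gene counts per region, over all RNA probes, were 71711 in bone (18126 to 631482) and 73148 in brain (13180 to 1183434) on the first plate. On the second plate they were 224227 in bone (26764 to 1019127) and 249081 in chest wall (40721 to 1156455). The deposited table of the first plate, which lists fewer genes and writes 0 as 1, had median totals of 71285 and 68411. The antibody barcodes added a median of 406373 counts in bone and 519769 in brain. The series asks what sets lesions that resist the drug apart, but the labels give no response per region, so only metastatic sites on the same plate were compared.

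Detection differed little between bone and brain and strongly between bone and chest wall. The median share of genes above the limit of quantification was 25.97% in bone and 25.86% in brain on the first plate. On the second it was 10.4% in bone and 45.4% in chest wall. Negative probes, which measure background, took a median of 0.142% of counts in bone and 0.225% in brain, then 0.372% in bone and 0.118% in chest wall. The 3 transcripts PTBP1, MZT2B and ADAM15, singled out after their values were seen, took a median of 11.4% of the counts of bone on the second plate and 2.03% in chest wall. The epithelial list averaged 8.07 ± 1.26 log2 CPM in brain (SD, n = 39), 7.53 ± 1.11 in bone on the first plate (n = 47), 6.92 ± 1.11 in bone on the second (n = 61) and 7.65 ± 1.41 in chest wall (n = 15). The leukocyte list averaged 6.54 ± 1.26, 6.76 ± 1.09, 6.35 ± 0.96 and 5.81 ± 1.40 in the same order. Regions had been picked by cytokeratin and CD45 staining, so neither list measures the makeup of a whole lesion.

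**Figure D1:**
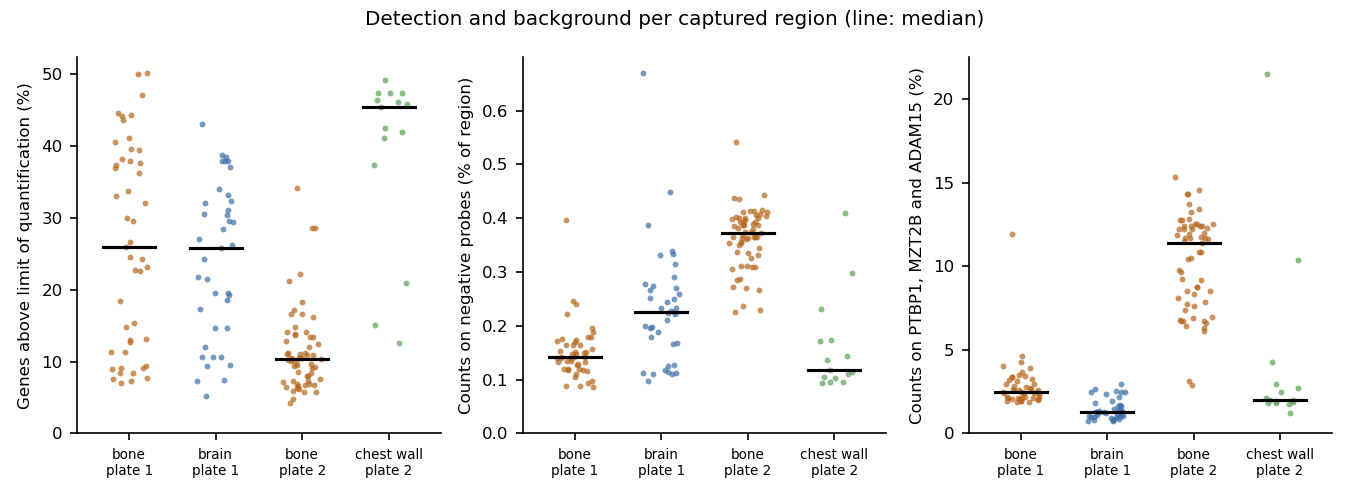
Points are the 162 regions by tissue and plate, lines are medians, and the vertical axes give the percent of genes above the limit of quantification, the percent of counts on negative probes and the percent of counts on PTBP1, MZT2B and ADAM15. Bone on the second plate had the lowest median detection (10.4%) and chest wall the highest (45.4%).

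Bone regions carried more immunoglobulin transcripts than brain regions and less RNA of the HER2 amplicon, the block of neighbouring genes that is co-amplified with ERBB2. IGKC, the kappa light chain made by plasma cells, averaged 12.50 ± 2.68 log2 CPM in bone (SD, n = 47) and 5.50 ± 0.73 in brain (n = 39). It was higher in bone in 100% of region pairs, with a log2 difference of 10.39 ± 0.78 (SE). The heavy chains IGHG1 to IGHG4, whose sequences are too alike to be read separately, differed by 9.32 to 10.59, and JCHAIN, which joins antibody units, by 4.19 ± 0.48. ERBB2, the gene of the drug's target HER2, stood at 7.65 ± 1.33 in bone and 9.54 ± 1.93 in brain, a log2 difference of -2.38 ± 0.31. Its neighbour MIEN1, a membrane-anchored protein linked to cell migration, differed by -2.05 ± 0.25. SCGB2A2, which encodes mammaglobin, a secreted protein of breast epithelium, differed by -5.70 ± 0.57, and lumican (LUM), a proteoglycan of collagen matrix, by 3.12 ± 0.34. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, p was 7.3e-19 for IGKC, 2.4e-11 for JCHAIN, 1.1e-09 for ERBB2, 1.1e-10 for MIEN1, 1.1e-13 for SCGB2A2 and 4.7e-12 for LUM. IGKC exceeded the limit of quantification in 15.4% of brain regions and IGHG1 in 2.56%, so the size of their differences depends on background in brain.

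Among 10763 genes tested with edgeR, 4023 passed the adjusted p and 669 also passed the fold, 281 higher in bone and 388 lower. P-values over regions are too small because the regions share lesions. The study has 2 bone and 2 brain lesions, and the labels do not give which of them were on this plate. Stretches of wells of a single tissue also differed in many genes. Between the stretches of bone wells (23 and 24 regions) 987 genes were called, and between those of brain wells (21 and 18 regions) 1282. Single bone stretches against single brain stretches, groups of like size, gave 924 to 1477 genes. Called with the same sign in each of the 4 bone and brain pairs of stretches were 76 genes, 43 higher in bone and 33 lower. IGKC, IGHG1 to IGHG4, JCHAIN, LUM, ERBB2, MIEN1 and SCGB2A2 are among them. So are CYP4F8, a cytochrome P450 of fatty acid oxidation, with a log2 difference of 5.53 ± 0.60, and HGD, an enzyme of tyrosine breakdown, with -3.25 ± 0.25. FADS2, a fatty acid desaturase, differed by -3.24 ± 0.33 and SERPINA3, an acute-phase protease inhibitor, by -3.68 ± 0.45. Their size depended on the stretches: over the 4 pairs CYP4F8 ran from 2.12 to 6.95, FADS2 from -4.54 to -1.49 and SERPINA3 from -4.82 to -1.29. MDK, a heparin-binding growth factor (-3.35 ± 0.39), SCGB1D2, the partner of mammaglobin (-3.72 ± 0.44), and CLEC3A, a cartilage lectin (-3.15 ± 0.42), were called over all regions but not in each pair. MDK reached 0.43 and CLEC3A 0.98 in the pair furthest in the other direction.

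**Figure D2:**
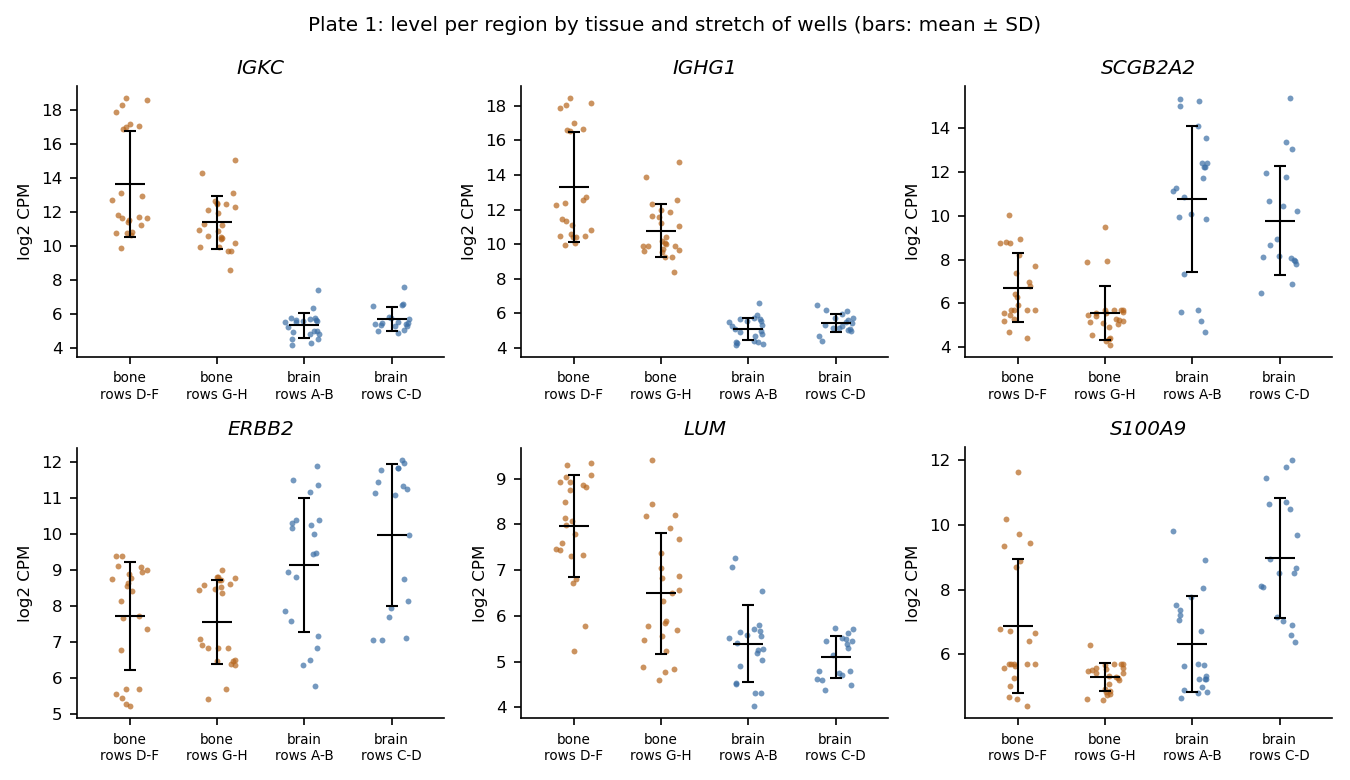
Points are the 47 bone and 39 brain regions of the first plate, parted by stretch of adjacent wells, on vertical axes of log2 CPM, with the mean and SD as bars. Every bone region lay above every brain region for IGKC and IGHG1, SCGB2A2 and ERBB2 had lower means in both bone stretches than in both brain stretches, LUM had higher ones, and the means of S100A9 crossed.

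Of the 11 measured HER2 amplicon genes, 9 fell in bone against brain and none rose. Only 2 of the 9, ERBB2 and MIEN1, were also called in each pair of stretches. An example of the others is TCAP, a muscle sarcomere gene carried along in the amplicon (-1.43 ± 0.19). It was -0.13 in the furthest pair of stretches. CDK12 (-0.98) and PPP1R1B (-0.34) did not pass. The B and plasma cell list had 4 of 6 members higher in bone, IGKC, IGHG1, JCHAIN and MZB1, a chaperone of antibody secretion (1.97). Camera gave an adjusted p of 2.0e-07 for the amplicon and 1.3e-05 for the B and plasma cell list, each with an adjusted p = 0.135 with an estimated correlation. In the extracellular matrix list 6 of 14 members rose, among them LUM, biglycan (BGN, 1.69 ± 0.36) and the collagen chain COL1A1 (1.74 ± 0.42), and SPARC, a collagen-binding protein, fell. BGN and COL1A1 turned in 1 or more pairs of stretches, to -0.33 and -1.32 at the furthest. In the epithelial list KRT19, a keratin of simple epithelia (-1.17 ± 0.37), and CDH1, the adhesion protein E-cadherin (-1.46 ± 0.29), fell among 8 members, and EPCAM, an epithelial adhesion molecule, was not called (-0.80 ± 0.20). In the MHC class II list 1 of 9 members rose, a polymorphic gene that is not named here. Camera's adjusted p was 0.0016 for the matrix list and 0.0392 for the epithelial and the MHC class II lists, and for all 3 adjusted p = 0.818 with an estimated correlation. In these 5 lists the counts were the same adjusted over the list alone. With epithelial and leukocyte levels as covariates, KRT19 gave 0.01, CDH1 -0.95 and ERBB2 -1.77. The epithelial level is the mean of the epithelial list, KRT19 and CDH1 included, so the shrinking of these 2 is partly built in.

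The S100 proteins and their receptor RAGE, which the series title names, did not move together between bone and brain. Of 12 S100 genes measured, S100A1, a calcium sensor of muscle, rose (1.11 ± 0.21), while S100A7, psoriasin (-2.29 ± 0.47), and S100A9, a subunit of calprotectin from neutrophils and monocytes (-1.58 ± 0.49), fell; 9 were not called. S100A8, the partner of S100A9, differed by -0.61 ± 0.47. Adjusted p from edgeR's quasi-likelihood test was 0.0068 for S100A9 and 0.32 for S100A8. AGER, the gene of RAGE, differed by 0.06 ± 0.20 (edgeR adjusted p 0.85) and exceeded the limit of quantification in 12.8% of bone and 5.13% of brain regions, so its level was mostly background. Of 19 genes of RAGE signalling, IKBKB, a kinase that activates NF-kB, rose by 2.08 ± 0.21 and 18 were not called. Camera's adjusted p was 0.715 for the S100 list and 0.860 for the RAGE list, and counts were the same adjusted over the list alone. S100A9 was not stable within tissues: it averaged 6.88 ± 2.07 and 5.30 ± 0.42 in the stretches of bone wells (SD, n = 23 and 24) and 6.32 ± 1.49 and 8.98 ± 1.84 in those of brain wells (n = 21 and 18). Its bone minus brain difference ran from -5.53 to 1.66 over the 4 pairs of stretches, and with the background share as a covariate it was -0.72, with an edgeR adjusted p of 0.425 (0.003 to 0.425 over 16 alternatives, which count only the furthest pair). S100A7 and S100A1 turned too, to 2.72 and -0.18 at the furthest. P-values over regions are too small because the regions share lesions.

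TOP1, the enzyme that the drug's payload inhibits, differed by -0.29 ± 0.15 between bone and brain (edgeR adjusted p 0.12). Of 13 genes in the topoisomerase and DNA damage list, ATM, a kinase that senses double-strand breaks, rose (1.06 ± 0.21) and 12 were not called. ATM was 0.97 with each region centred on its median, 0.74 with epithelial and leukocyte levels as covariates and 0.65 in 1 pair of stretches, each time not called. Camera's adjusted p was 0.788 and the count was the same adjusted over the list alone. Genes of the brain cell lists went both ways, and whether the RNA of those that rose came from such cells was not tested. Of 3 astrocyte genes GFAP, a filament protein, fell in bone (-2.65 ± 0.51), GJA1, a gap junction protein, rose (1.71 ± 0.22) and SLC1A3 was not called. Of 3 oligodendrocyte genes MBP, a myelin protein, fell (-1.85 ± 0.38), and CNP and MAG were not called. Of 4 microglia genes TMEM119 rose (1.30 ± 0.23), and the neuron list had 1 measured gene, RBFOX3, not called. Camera's adjusted p was 0.736 for astrocytes, 0.131 for oligodendrocytes and 0.560 for microglia, and these counts were the same adjusted over the list alone. GFAP was -0.48, GJA1 0.88 and TMEM119 0.75 in the furthest pair of stretches, none of them called, and MBP was -0.78 and not called with the background share as a covariate. PTPRC, which encodes the CD45 used to choose immune areas, differed by -0.14 ± 0.46, and 0 of 6 pan-leukocyte genes were called, also adjusted over the list alone. B2M, the light chain of MHC class I, differed by 0.38 ± 0.29. These p-values, too, are too small because regions share lesions.

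Antibody barcodes also differed between bone and brain, but the proteins behind them are not named in the files. Of 580 barcodes, 110 were called with limma, 40 higher in bone and 70 lower. The largest fall was in RTS0049003, with a log2 difference of -2.80 ± 0.20 (SE, n = 47 and 39), followed by RTS0048994 with -2.47 ± 0.19. The largest rises were in RTS0048744, 2.42 ± 0.42, and RTS0049255, 2.24 ± 0.40. Limma's Benjamini-Hochberg adjusted p was 1.5e-21 and 2.8e-20 for the first pair and 1.1e-06 and 2.3e-06 for the second. Regions share lesions, so these p-values are too small. Stretches of wells of a single tissue, which are smaller groups, differed in 116 barcodes within bone and 122 within brain.

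Single epithelial genes differed widely between bone and chest wall on the second plate. Several genes of luminal breast epithelium were higher in bone: SCGB2A2 averaged 9.39 ± 3.20 log2 CPM in bone (SD, n = 61) and 4.70 ± 0.64 in chest wall (n = 15), a log2 difference of 7.15 ± 1.12 (SE). It also differed by 2.997 between the stretches of bone wells (edgeR adjusted p 2.1e-05). FOXA1, a factor that opens chromatin for the oestrogen receptor, differed by 3.75 ± 0.51 and ESR1, the receptor itself, by 2.27 ± 0.26. AGR2, an endoplasmic reticulum protein of secretory epithelium, differed by 5.15 ± 0.74 and TFF3, a mucosal peptide, by 5.08 ± 0.74. Some genes of basal and stratified epithelium were higher in chest wall: the keratins KRT5 and KRT17 differed by -3.31 ± 0.16 and -2.60 ± 0.21, and the desmosomal cadherin DSG3 by -4.41 ± 0.19. CRABP1, a carrier of retinoic acid, averaged 4.99 ± 0.66 in bone and 10.21 ± 1.82 in chest wall, a difference of -6.16 ± 0.21 with bone higher in 0% of region pairs. SFRP1, a secreted antagonist of Wnt (-5.31 ± 0.20), and PHGDH, the entry enzyme of serine synthesis (-5.20 ± 0.20), also fell. So did ATF3 and EGR1, transcription factors induced early by stress and growth signals (-5.15 ± 0.21 and -4.48 ± 0.19). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, p was 7.4e-08 for SCGB2A2, 1.5e-09 for FOXA1, 1.5e-12 for ESR1, 9.5e-37 for KRT5, 2.9e-38 for DSG3 and 4.7e-46 for CRABP1. The size of several of these differences depends on background in the lower tissue. In bone CRABP1 exceeded the limit of quantification in 1.64% of regions, SFRP1 in 0% and PHGDH, KRT5 and DSG3 in 3.28%, and in chest wall FOXA1, ESR1 and AGR2 did in 0%. Over 14 alternatives KRT17 lost its call in 1 and the other genes of this paragraph stayed called, but CRABP1 shrank to -4.56, SFRP1 to -3.28, PHGDH to -3.05, DSG3 to -2.77 and ATF3 to -2.75 at the least. SCGB2A2 ranged from 5.30 to 12.13, FOXA1 from 3.52 to 6.24 and AGR2 from 4.61 to 7.99. The luminal list as a whole lost its call with an estimated correlation (camera adjusted p = 0.752).

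Of 13970 genes tested with edgeR on the second plate, 9428 passed the adjusted p and 3442 also passed the fold, 1882 higher in bone and 1560 lower. P-values over regions are too small, and the chest wall regions come from 1 lesion, so the differences cannot be set against a spread between chest wall lesions. Against each of the 2 stretches of bone wells (23 and 38 regions), 2278 genes were called with the same sign, 1200 higher in bone and 1078 lower. SCGB2A2, FOXA1, ESR1, AGR2, TFF3, KRT5, KRT17, DSG3, CRABP1, SFRP1, PHGDH, ATF3 and EGR1 are among them. Of the 1882 genes higher in bone, 1608 (85.4%) exceeded the limit of quantification in fewer than 25% of bone regions, as did 81.2% of all genes tested. Of 139 negative probes put through the same fit, 112 were called higher in bone and 0 lower. The log2 differences of all 139 had a median of 1.25, and 95% lay between 0.77 and 1.85. FOXA1, ESR1, AGR2, TFF3 and SCGB2A2 differed by more than those probes and exceeded the limit in 59.02% to 72.1% of bone regions. With the background share as a covariate, 1047 genes were called, 704 higher and 343 lower, and KRT17 (-1.11) was no longer called. On this plate that share ran from 0.226% to 0.541% in bone and from 0.0938% to 0.409% in chest wall (medians 0.372% and 0.118%). The share thus largely follows tissue, and calls lost with it do not tell background from tissue. With DESeq2 size factors 3374 were higher and 943 lower. The median difference of all genes was 0.10 with TMM and 0.39 with those size factors.

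**Figure D3:**
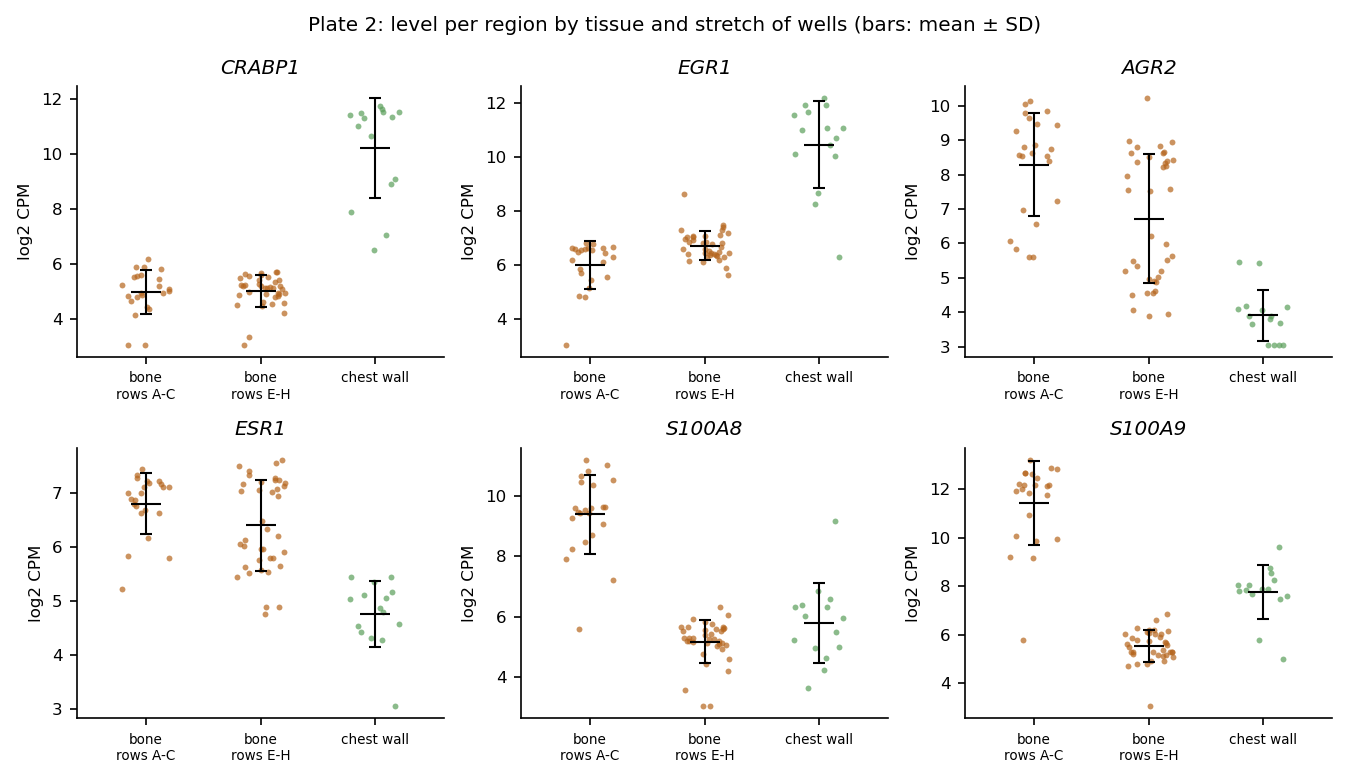
Points are the 61 bone regions of the second plate, parted into wells before and after the chest wall wells, and the 15 chest wall regions, on vertical axes of log2 CPM, with the mean and SD as bars. CRABP1 and EGR1 were higher in chest wall than in both bone stretches, AGR2 and ESR1 were lower there, and S100A8 and S100A9 in chest wall lay between the means of the bone stretches.

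In the luminal epithelial list 11 of 16 members rose in bone against chest wall and none fell, ESR1, FOXA1, AGR2, TFF1 and TFF3 among them (TFF1, 3.69 ± 0.63). Of 4 keratinocyte genes, KRT5, KRT17 and DSG3 fell, and KRT10, a keratin of outer skin layers, rose. In the endocytosis and lysosome list 10 of 15 members fell, such as LAMP2, a lysosomal membrane protein (-1.95 ± 0.18), ATP6V1A, a subunit of the proton pump (-1.49 ± 0.13), and RAB5A, a GTPase of early endosomes (-1.28 ± 0.13). In the oxidative phosphorylation list 7 of 13 fell, among them the respiratory chain subunits COX4I1 (-1.63 ± 0.15), NDUFB8 (-1.47 ± 0.14) and the ATP synthase subunit ATP5F1A (-1.38 ± 0.14). Camera's adjusted p was 0.0205 for the luminal list, 9.6e-05 for the keratinocyte list, 1.1e-05 for the lysosomal list and 6.0e-05 for oxidative phosphorylation. In the same order it was adjusted p = 0.752, 0.022, 0.112 and 0.583 with an estimated correlation. Against the bone wells after the chest wall wells alone the luminal median was 1.48 and camera's call was lost. Counts were the same adjusted over the list alone, and p-values over regions are too small because the regions share lesions. With the background share, which was higher in bone, as a covariate, LAMP2 gave -0.01, ATP6V1A -0.35, RAB5A -0.67, COX4I1 -0.49, NDUFB8 -0.34 and ATP5F1A -0.09, none of them called. Because that share largely follows tissue here, these lost calls do not tell background from tissue.

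**Figure D4:**
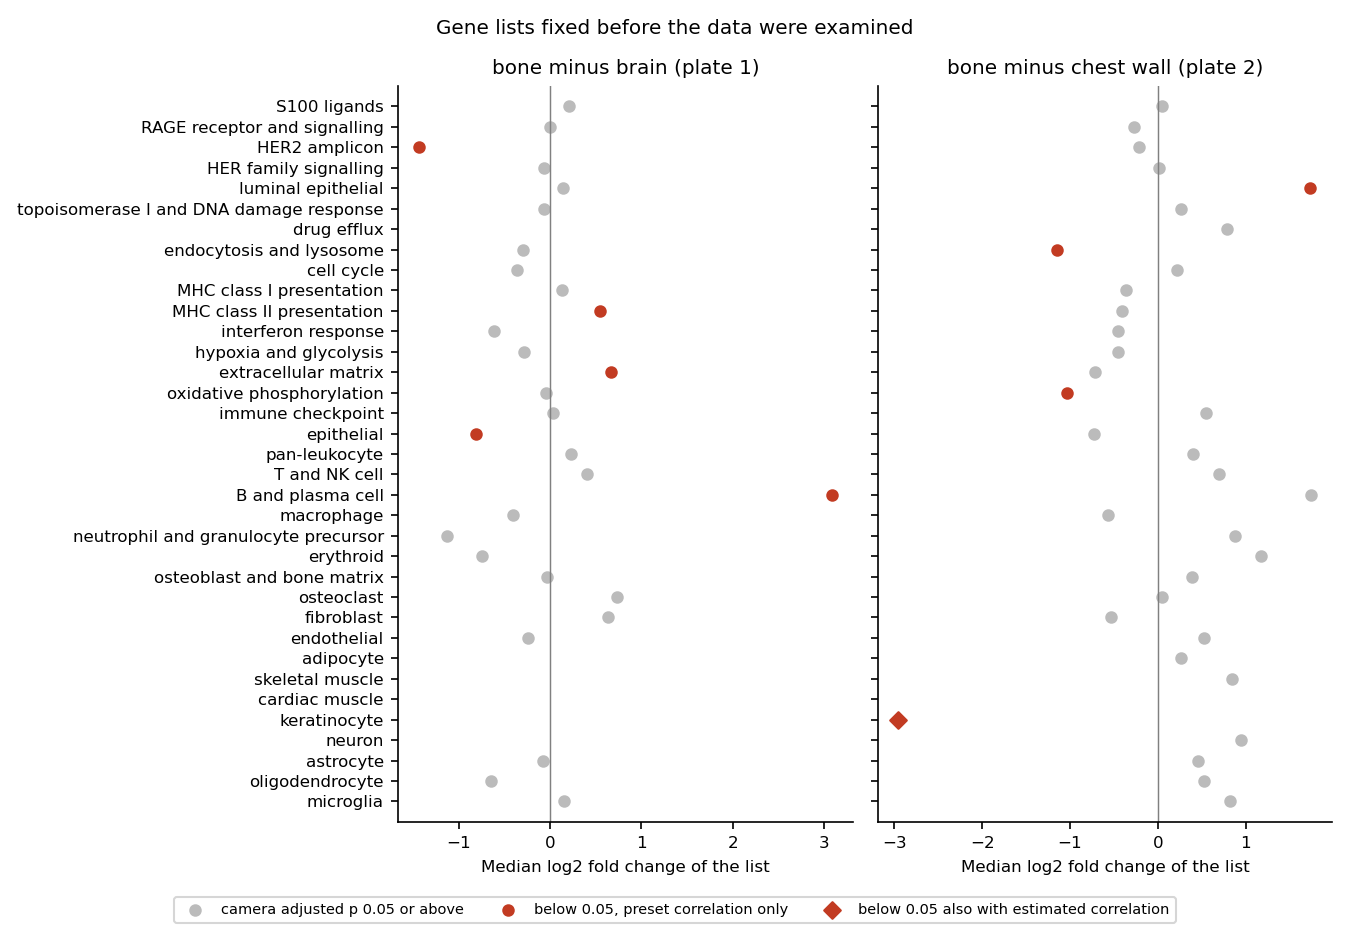
Each point is the median log2 difference of the tested genes of a list (bone minus brain on the left, bone minus chest wall on the right), in colour where camera's adjusted p was under 0.05 and as a diamond where it stayed so with an estimated correlation. The HER2 amplicon had a median of -1.43 in bone against brain, the luminal list one of 1.73 in bone against chest wall, and the keratinocyte list alone is a diamond (-2.95).

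ERBB2 was higher in bone than in chest wall by 1.14 ± 0.32 (edgeR adjusted p 0.0014), at 7.33 ± 1.16 against 6.48 ± 0.70 log2 CPM. The difference lay within the range of the negative probes in the same comparison. ERBB2 itself exceeded the limit of quantification in 67.2% of bone and 86.7% of chest wall regions, so that match does not show that background made the difference. With the background share as a covariate the difference was 1.84 and its adjusted p from edgeR 0.0635, and over 14 alternatives the difference ran from 0.97 to 1.84 and the adjusted p from 2.3e-17 to 0.0635. In the amplicon list TCAP also rose (1.31 ± 0.18), within the range of the negative probes. PPP1R1B, a regulator of protein phosphatase 1, fell (-2.26 ± 0.23), but turned with the background share as a covariate. The other 8 of 11 were not called (camera adjusted p 0.754). TOP1 fell by 1.15 on the log2 scale (SE 0.12, edgeR adjusted p 5.3e-15), and with the background share as a covariate the difference was -0.47 (edgeR adjusted p 0.274, from 6.9e-20 to 0.274 over 14 alternatives). Of 11 MHC class I genes 4 fell, B2M among them (-1.81 ± 0.34), with a camera adjusted p of 0.446. Of 11 immune checkpoint genes, VTCN1 (-3.87 ± 0.33) and CD276 (-1.94 ± 0.14), ligands that inhibit T cells, fell. PDCD1LG2, a ligand of PD-1 (1.19 ± 0.25), and CTLA4 and TIGIT, inhibitory receptors on T cells, rose, all 3 within the range of the negative probes, and camera's adjusted p was 0.901. PDCD1LG2 exceeded the limit of quantification in 3.28% of bone regions. KRT19 (-0.64 ± 0.45), EPCAM (-0.23 ± 0.19), PTPRC (0.30 ± 0.46) and COL1A1 (-0.54 ± 0.39) were not called, and KRT19 turned to 3.62 with the background share as a covariate. With the same covariate B2M gave -1.32, VTCN1 -0.59, PDCD1LG2 0.40 and CTLA4 0.20, none of them called. Since that covariate largely follows tissue on this plate, the changes under it do not tell background from tissue. Counts for these lists were the same adjusted over the list alone, and p-values over regions are too small because the regions share lesions.

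Calprotectin genes set bone regions of the second plate apart from one another. S100A8 averaged 9.38 ± 1.30 log2 CPM in the stretch of bone wells before the chest wall wells (SD, n = 23), 5.18 ± 0.72 in the stretch after them (n = 38) and 5.79 ± 1.31 in chest wall (n = 15). S100A9 averaged 11.43 ± 1.73, 5.52 ± 0.66 and 7.75 ± 1.11 in the same order. Between the stretches of bone wells the log2 differences were 4.79 for S100A8 and 6.59 for S100A9, with edgeR adjusted p of 5.2e-25 and 6.9e-28. Over all bone regions S100A8 differed from chest wall by 2.22 ± 0.77 and S100A9 by 2.58 ± 0.93, with edgeR adjusted p of 0.0095 and 0.0123. Against the second stretch alone both turned, to -1.001 and -2.62, and with epithelial and leukocyte levels as covariates S100A9 was 1.96 and not called. Of 17 S100 genes 5 rose, S100A7, S100A8, S100A9, S100P and S100Z, and 5 fell, S100A1 (-4.39 ± 0.30), S100A4, S100A10 (-1.67 ± 0.17), S100A11 (-1.59 ± 0.23) and S100A13. With the background share, which largely follows tissue on this plate, as a covariate S100A10 (-0.90) and S100A11 (1.02) were not called. Camera's adjusted p was 0.388, and counts were the same adjusted over the list alone. AGER differed by 0.90 ± 0.19, under the fold of a call, and exceeded the limit of quantification in 0% of bone and 6.67% of chest wall regions, so its level was mostly background. These p-values are too small because regions share lesions.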

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

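The tests on immediate early genes, the fit of the negative probes and the comparisons of well stretches within a tissue of the first plate were chosen only after the results were seen; the other tests were set before. The immediate early genes named were also chosen after.

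A signal appeared in regions no comparison used. Of 28 regions with a count file that are in neither table, 26 held more than 1 count, and in 8 of them at least 10% of genes exceeded the limit of quantification, 4 of bone on the second plate and 4 of chest wall. The chest wall regions left out had a median of 21.2% of genes above that limit and a highest value of 31.8%. The reason they were left out is not given in the sources used here.

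Of 100 splits of the regions into groups of the same sizes, 1, the real one, reached the 669 genes of bone against brain, and the highest other split gave 111. For bone against chest wall it was again 1 of 100, with 3442 genes against 75 in the highest other split, and for the antibody barcodes 1 of 100, with 110 against 0. A random mixing of regions is thus excluded, but regions of a lesion cannot be exchanged freely, so chance between lesions is not. Within the first plate the stretches of bone wells differed in 987 genes and 116 barcodes and those of brain wells in 1282 and 122. A structure of the regions besides tissue was thus present. Single bone stretches against single brain stretches, groups of like size, differed in 924 to 1477 genes.

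Genes higher in bone than in chest wall were many and mostly faint. Of the 1882, 85.4% exceeded the limit of quantification in fewer than 25% of bone regions, but so did 81.2% of all genes tested, so this share, set as the test of background, decides nothing. Of the negative probes, 80.6% were called higher in bone in the same fit, and 97.7% of the 1608 faint genes differed by no more than the upper end of the probes' 95% range (1.85), so a higher level of untargeted signal in bone is a candidate explanation for those genes. Differences between stretches of wells of one tissue gave 398 genes, 11.6% of the number between tissues, which argues against wells alone as the source. The cause stays open for all of these genes, since a difference within the probes' range does not show that background made it. Among the 274 better detected genes, 66 passed the range, FOXA1, ESR1 and AGR2 among them. A difference between tissues or patients was not tested, since 1 chest wall lesion was sampled.

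Immunoglobulin transcripts were far higher in bone than in brain, with a median log2 difference of 8.59 over 10 genes, 8 of them called. A fault of the immunoglobulin probes alone is argued against by 12 other plasma cell genes, 7 of them called higher in bone and 0 lower. Their median was 1.04, against -0.29 to 0.28 in the central 95% of 10000 expression-matched random lists. Those lists drew genes one by one, so the range is too narrow for genes that move together. For the B and plasma cell list the estimated correlation was 0.51, and camera's adjusted p with it was 0.135. More leukocytes of every kind in the bone regions is argued against by the T and NK cell and pan-leukocyte lists. Their medians were 0.41 and 0.23, both under 50% of 1.04, and 0 pan-leukocyte genes were called. In the T and NK cell list, however, 8 of 9 genes leaned higher in bone, and CD2 and TRAC were called higher. These 2 exceeded the limit of quantification in at most 31.9% of the regions of a tissue. The size of their differences thus depends on background, and a smaller rise of T cells is not excluded. RNA from plasma cells in the bone regions of the first plate remains as a hypothesis, found and tested on the same data; site, lesions and the choice of segments were not told apart. On the second plate 7 of 10 immunoglobulin genes were higher in bone (median 2.73) while the other plasma cell genes had a median of 0.30, inside -0.49 to 0.56, so the same test there does not exclude a fault of the probes.

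Immediate early genes, which respond to stimuli within minutes, were lower in bone on both plates. Against brain 11 of 19 fell, among them FOS (-2.78 ± 0.22) and EGR1 (-2.31 ± 0.24), and against chest wall 20 of 21, among them FOS (-3.83 ± 0.22) and MYC (-4.37 ± 0.22). Lower detection of all transcripts of that level in bone is argued against by the medians. They were -1.15 against -0.38 to 0.24 in level-matched random lists for brain, and -2.75 against -1.72 to -0.88 for chest wall. The random lists drew genes one by one, so for genes regulated together these ranges are too narrow and the argument is weakened. Handling of the tissue before fixation, treatment of bone before sectioning and a difference between lesions could each lower these genes and were not tested, so none is excluded.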

How the results depend on the processing

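The alternatives on background, on regions of low detection, on dominant probes and on the floor of 1 were chosen after seeing the data. So were the pairs of well stretches of the first plate and the counts of genes called in every pair. The others were set before. Of the values of named genes and lists under all alternatives, 3325 kept their side of the threshold, 126 newly passed it and 247 no longer did. Another 30 changed direction with a call in the main or the alternative fit. For named genes, changes of direction without a call in either fit are counted among the 3325. Of the counts of calls, 92 stayed within 1.5 times, 12 rose by more and 15 fell by more. No paired analysis was possible because the replicate numbers follow the order of the samples and tie no region to another. Not run for want of antibody names were scaling by control antibodies, adjustment for pan-cytokeratin and CD45 protein, and the comparison of RNA and protein with its alternatives; a pseudocount was not applicable to counts. Dropping the minimum fold left 4023 genes in bone against brain (1985 higher, 2038 lower), 9428 in bone against chest wall (5167 and 4261) and 350 barcodes (198 and 152), by construction. Called in every pair of well stretches were 76 genes (43 and 33) and, against chest wall, 2278 (1200 higher). Against chest wall, DESeq2 size factors gave 3374 higher and 943 lower and DESeq2's test 3380 and 968, with the median of all genes at 0.39 instead of 0.10. Only genes above the limit of quantification gave 1645 (667 and 978), fewer genes being tested, and the background share as a covariate gave 1047 (704 and 343). Of the camera calls, 5 and 4, an estimated correlation left 0 for bone against brain and 1 for bone against chest wall, and the epithelial and leukocyte covariates gave 9 for brain.

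Under those covariates KRT19 turned to 0.01 (0.0092), and camera's direction for the luminal list against brain turned from down to up, its median going from 0.144 to 0.759. KRT19 is itself part of the epithelial level, and the luminal list shares members with it, so neither turn is independent of the covariate. With the background share as a covariate CD68 turned to 0.25 in bone against brain, and in bone against chest wall BNIP3 turned to 0.31, PPP1R1B to 0.31, PGK1 to 0.54, S100A11 to 1.02, CLDN7 to 0.72 and KRT19 to 3.62. Between bone and chest wall that share largely follows tissue, so these turns do not tell background from tissue. Against the bone wells after chest wall, S100A8 was -1.001 and S100A9 -2.62. In the pair of stretches furthest against the main direction, bone minus brain was 0.43 for MDK, 0.98 for CLEC3A, -0.44 for KRT10, -0.18 for S100A1, -0.15 for TFF1, 0.60 for IFIT1, 2.72 for S100A7, -0.33 for BGN, 0.41 for TYMS, -1.32 for COL1A1, 0.30 for VWF, 0.14 for SPP1, 0.10 for CLDN5, 1.66 for S100A9, 1.14 for LCN2, 0.34 for CD68, -1.42 for COL1A2, 2.44 for S100A8 and 2.08 for TNNT1. The cause was not tested. Over the alternatives and all 4 pairs of stretches, ERBB2 in bone against brain ranged from -2.87 to -1.77 and IGKC from 7.08 to 11.63. How detection goes with depth differed by plate, in a comparison chosen after seeing the data. On the first plate the share of genes above the limit of quantification followed the gene counts, with a Spearman correlation of 0.851 in bone and 0.863 in brain. With the share of negative probes the correlation was weaker, -0.287 in bone and -0.539 in brain. In bone on the second plate detection followed the share of negative probes instead (-0.732, against 0.0431 with gene counts), and in chest wall both (-0.806 and 0.506). The limit is itself computed from the negative probes, and in many regions of the first plate it stood at its floor of 2. These correlations thus follow partly from the definition of the limit, and the difference between plates cannot be read as a property of the tissue.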

Other observations

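The genes of the next paragraph, and IGKC and JCHAIN against chest wall, were singled out after their values were seen, and no test below was set beforehand except those on the gene lists.

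Other genes called in each of the 4 pairs of well stretches between bone and brain belong to no list fixed beforehand, and no group of them was tested. NQO1, a quinone reductase, differed by -3.00 ± 0.28 (SE, n = 47 and 39), MGST1, a glutathione transferase of membranes, by -2.41 ± 0.27 and FTH1, the iron-storing ferritin heavy chain, by -1.55 ± 0.15. GDF15, a stress-induced cytokine, differed by -2.48 ± 0.27. SREBF1, a transcription factor of lipid synthesis, differed by -1.21 ± 0.18. AQP3, a water and glycerol channel, was higher in bone by 2.72 ± 0.33 and ZNF703, a zinc finger gene amplified in some luminal tumours, by 1.84 ± 0.24. With edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p ran from 3.6e-15 for NQO1 to 5.0e-08 for SREBF1, and these p-values are too small because regions share lesions.

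Interferon genes went both ways between bone and brain. Of 14, ISG15 (-1.27 ± 0.27), IFIT1 (-1.46 ± 0.29), IFI6 and IFIT3 fell and CXCL9, a chemokine that draws T cells, rose (2.61 ± 0.49), with a camera adjusted p of 0.210. In the pair of stretches furthest in the other direction ISG15 was -0.24, IFIT1 0.60 and CXCL9 1.18, none of them called, and with the background share as a covariate ISG15 (-0.83) and IFIT1 (-0.51) were not called either. Of 9 T and NK cell genes, CD2 (1.23 ± 0.39) and TRAC (1.32 ± 0.44) rose, with a camera adjusted p of 0.417. With epithelial and leukocyte levels as covariates they were 0.49 and 0.40, and in the furthest pair of stretches 0.93 and 1.098, in neither case called. In bone against chest wall, 8 of 9 B and plasma cell genes rose, such as IGKC (3.48 ± 0.94) and CD79A, a part of the B cell receptor (2.30 ± 0.46), and JCHAIN fell (-1.25 ± 0.55), with a camera adjusted p of 0.144. In that comparison 5 of 14 matrix genes fell, among them SPARC (-3.37 ± 0.29) and BGN (-3.10 ± 0.26), with a camera adjusted p of 0.248. With the background share, which largely follows tissue on the second plate, as a covariate SPARC was -1.98 and still called, and BGN was -1.43 and not called. The counts were the same adjusted over the list alone.

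The table of the first plate leaves out 7881 genes of the second table. In the count files of the first plate 0 of them exceeded the limit of quantification in 25% of the regions of either tissue. Of the 3205 tested, edgeR called 10 higher in bone and 117 lower.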
